A study of Mus musculus with 3 samples.

How the data were processed

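Spleen cell suspensions of wild-type mice were profiled with 10x Genomics single-cell RNA sequencing in 3 libraries, 1 per group. The groups were control without irradiation, IR with 8.5 Gy and a "colvent control", and IR_HSO with 8.5 Gy and HSO. The label "colvent control" was read as a control vehicle, which is uncertain. The series title gives HSO as hemp seed oil. The labels give neither the time between irradiation and sampling nor the dose, route or schedule of HSO, nor how many mice a library holds. The deposited values were raw unique molecular identifier (UMI) counts per gene and cell barcode, made by the authors with Cell Ranger 7.0.1 per the file headers. Per the submitters' processing notes the genome build was GRCm39. The annotation release and the alignment settings are not stated. The deposited barcodes were those left after cell calling, and none held under 500 UMIs. Raw reads and the uncalled droplets were not used here. The features listed 56980 genes, the same in all 3 libraries, and gene names came from them. The reference at hand was of another build, so no coordinates were used, and 7 fixed symbols that the features did not list were matched through older symbols.

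Marker genes of 15 cell classes, 23 gene lists, the cell filter, the comparisons, the rule for named genes and the first set of other settings were set before the data were examined. Barcodes were kept with at least 200 genes, at least 500 UMIs and under 10% mitochondrial UMIs. The filter removed 450 of 9520 barcodes in control, 655 of 13509 in IR and 2125 of 12710 in IR_HSO. Most of these, 357, 643 and 2102, had 10% or more mitochondrial UMIs, or 3.75% of barcodes in control, 4.76% in IR and 16.5% in IR_HSO. A Scrublet-type doublet score was computed per library, and the cells with the highest scores were removed at 0.8% of cells per 1000 cells. That removed 658 cells in control, 1322 in IR and 896 in IR_HSO, and 8412, 11532 and 9689 cells were kept. The kept cells had median UMI numbers of 4124.5, 3003.5 and 3194.

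Counts per cell were scaled to 10000 and log-transformed. Clustering of all libraries together without integration used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 with a fixed seed, and gave 38 clusters. Immunoglobulin, T cell receptor, mitochondrial, ribosomal and haemoglobin genes took no part in the choice of variable genes. A cluster took the class with the highest mean z-score of its markers where at least 3 markers were detected in 10% of its cells. It stayed unnamed with under 20 cells, where its 10 top genes held more markers of another class, or where its median UMI number was under 1/3 of that of its libraries and no own marker was a top gene. Each named class is to be read as X-like, since names rest on markers only. The B, T and NK cell classes were clustered again, each sub-cluster was named by the same rule beside all other clusters, and sub-clusters that took another name left their class. The T cell class had 24 sub-clusters at the end.

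Several parts of the naming were set after clusters had been seen. These were the floor of 0.25 on the marker standard deviation, the reference of the top genes, the second clustering, the minimum of 20 cells per cluster and the minimum score of 0.5 for a T cell subset. T cells whose sub-cluster met no subset rule made up 47.6% of the class in control, 60.8% in IR and 43.0% in IR_HSO. Unnamed clusters held 18, 247 and 267 cells.

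Within a class, counts were summed per library and scaled to the class total as CPM. A log2 ratio added 1 CPM to both sides. Gene ratios carry exact conditional 95% intervals of the ratio of 2 counts. A list's value is the median log2 ratio of its members with at least 5 CPM in either library, with an interval from 1000 Poisson resamplings. Members at least 1.5-fold higher or lower were counted, and the others are said to lie between. Each median is given a percentile among 10000 random lists matched on mean expression, as a description of these libraries. Class shares carry exact (Clopper-Pearson) 95% intervals. Shares of cells with a UMI of a gene were taken after thinning each cell to 1000 UMIs. With 1 library per group there was no test and no p-value, and intervals cover counting error only. A gene at 0 in 1 library is given as a bound against 3 counts. This bound leaves out counting error in the other library, so the 95% limit of the ratio can lie nearer to no change.

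The 23 lists were p53 targets, DNA damage sensing and repair, pro-apoptotic, anti-apoptotic, proliferation, interferon response, NF-kB and inflammatory cytokine, immediate-early and stress, antioxidant, fatty acid oxidation and PPAR targets, fatty acid and sterol synthesis, oxidative phosphorylation, MHC class II presentation, MHC class I presentation, B cell receptor signalling, T cell receptor signalling and activation, inhibitory receptors and exhaustion, cytotoxicity, naive and homing, effector and memory T cell, immunoglobulin heavy constant, unfolded protein response, and survival cytokine receptors. Some genes stand in more than 1 list. Named genes were the 6 highest and 6 lowest log2 ratios in the B and T cell classes among genes with at least 50 CPM in either library. Their intervals take no account of this choice of extremes. Immunoglobulin, T cell receptor, mitochondrial, ribosomal protein, haemoglobin, predicted and sex-linked genes and markers of other classes were left out of that choice. Any p53 target and up to 4 members of each other list could be named as well. Members named as examples of a list were taken from the 4 with the largest absolute log2 ratio. Other genes named in the text were chosen after their values were seen. Results of some list members are not reported here.

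The steps were tested on simulated counts drawn from the real means with Poisson error alone. The 200 changed genes were drawn from those with at least 50 CPM over both libraries together. The direction of genes at lower levels and differences between libraries were therefore not covered. In the T cell class the right direction was found for 100% of 67 genes changed 1.5-fold, for IR over control (10163 genes measured) and for IR_HSO over IR (10448). In the B cell class 98.5% of 67 such genes had the right direction for IR over control (10437 measured), and 91.0% for IR_HSO over IR (11419).

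Other settings chosen at the start were a stricter filter (500 genes, 1000 UMIs, 5% mitochondrial), a looser one (20% mitochondrial, no UMI minimum), no doublet removal, resolution 2, each library clustered alone, classes of single cells from their own markers, lymphocytes alone as denominator, other scalings, the mean over cells, no low-count filter, 20 CPM as minimum, and unthinned shares. Settings added after the data were seen counted sub-cluster T cell 20 with T cells, took T cell RNA out of the B cell class at the level of Cd3 in it, left out Rn18s-rs5, sub-clusters of low UMI number or B cell sub-cluster 09, or used the regulatory sub-clusters or each T cell sub-cluster with at least 20 cells in both libraries alone. Those for single genes, T cell lists other than p53 targets, and subset, NK and plasma cell shares were added then too. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.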

Results

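Spleen cells of wild-type mice were sequenced in 3 libraries, which held 47298108 UMIs over 9520 barcodes for control, 50836313 over 13509 for IR and 45636807 over 12710 for IR_HSO. IR and IR_HSO came from mice given 8.5 Gy, a dose that damages DNA and kills lymphocytes. IR came with what was read as the control vehicle, and IR_HSO with HSO. The series title names hemp seed oil and radioprotection of splenic lymphocytes as its subject, so IR against control asks what irradiation goes with in these cells and IR_HSO against IR asks what HSO goes with. Each group has 1 library, so no difference below has a replicate check, and every comparison is between libraries. The Y-linked gene Ddx3y stood at 132, 138 and 141 CPM in the T cell classes of control, IR and IR_HSO, and Xist, which marks female cells, had at most 5 UMIs in each. Mitochondrial genes took 2.25%, 2.37% and 3.84% of UMIs, ribosomal protein genes 25.1%, 21.8% and 20.8%, and the ribosomal RNA gene Rn18s-rs5 2.97%, 1.23% and 4.99%.

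Irradiation went with a nearly complete absence of B cells from the library and with T cells that carried high levels of p53 targets. B cell-like cells were 45.7% [44.6, 46.8] of control cells and 0.893% [0.730, 1.08] of IR cells, or 3845 and 103 cells, a log2 ratio of -5.68 [-5.96, -5.40]. T cell-like cells were 40.6% [39.6, 41.7] of control and 68.9% [68.0, 69.7] of IR, a log2 ratio of 0.76 [0.72, 0.80]. In the T cell class Cdkn1a, which encodes the cell cycle inhibitor p21, was 190-fold [124, 307] higher in IR than in control, and Bax, a pore-forming killer of mitochondria, was 4.22-fold [4.04, 4.42] higher. Shares are relative, so a higher T cell share does not show that a spleen held more T cells.

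Other classes moved as well. NK cell-like cells, innate killers of stressed cells, were 366 of the control cells and 2657 of the IR cells, a log2 ratio of 2.40, and antibody-secreting plasma cell-like cells were 0.535% and 2.45%, or 1.74% and 2.47% with each library clustered alone. Monocyte-like cells went from 219 to 1, plasmacytoid dendritic cells, the main source of type I interferon, from 50 to 0 of 11532 cells, which allows a share of up to 0.0320%. Conventional dendritic cell-like cells were 2.53% and 0.919%. The erythroid name went to 168 cells in control and 5 in IR, of which 124 and all 5 came from the cycling sub-cluster T cell 20, first grouped with T cells. Its markers were mixed in control, since 38.7% of the 124 cells had a UMI of Cd3d, Cd3e or Cd3g, 66.9% of Cd79a or Cd79b and 56.5% of Hbb-bs. None of its 5 IR cells had a UMI of an erythroid marker, which left 44 erythroid cells in control and 0 in IR outside it. Haemoglobin genes took 0.608% of all control UMIs and 0.00462% of IR UMIs, while immunoglobulin genes took 2.08% and 6.02%.

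**Figure D1:**
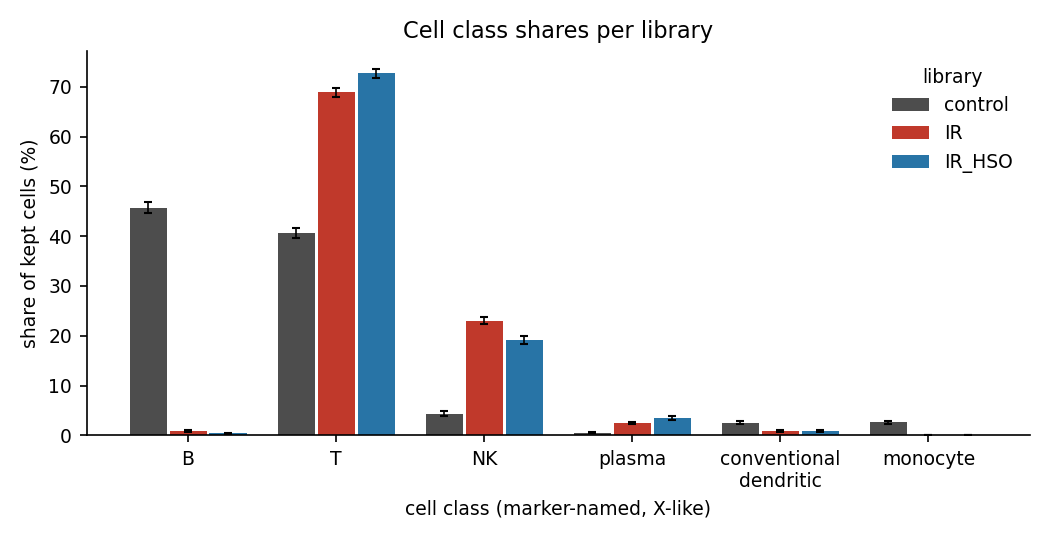
Bars give the share of kept cells in percent for 6 marker-named classes in the control, IR and IR_HSO libraries, with exact 95% binomial intervals that cover counting error only. B cell-like cells stood at 45.7% in control and under 1% in both irradiated libraries.

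Among T cells, CD8 cells were scarce after irradiation and regulatory cells, which restrain immune responses, took a larger share. Sub-clusters with CD8 markers held 32.6% of T cells in control and 2.52% in IR, a log2 ratio of -3.70 [-3.90, -3.49]. Regulatory sub-clusters held 6.03% and 12.5%, a log2 ratio of 1.05 [0.84, 1.26], and gamma-delta or innate-like ones 3.63% and 15.4%. CD4 sub-clusters held 10.1% and 8.76%. The classes came from different sub-clusters: control T cells lay most often in T cell 05, 08 and 04 and IR cells in T cell 01, 02 and 00, while CD8 cells of control lay in T cell 08 and 13 and those of IR mostly in T cell 11. Some sub-clusters without a subset name also had Cd8a among their top genes. Of these, T cell 06 held 45 cells of control and 565 of IR, and T cell 21 held 95 and 24. The CD8 share leaves them out. Sub-clusters of low UMI number held 5.35% of control and 12.2% of IR T cells.

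At matched depth CD8 genes and Foxp3 moved in the same direction as the CD8 and regulatory sub-clusters, while Cd4 did not follow the CD4 sub-clusters. The fall was smaller for cells with CD8 genes than for the CD8 sub-clusters. After thinning, which left out 44 of 3419 control and 728 of 7944 IR T cells, Cd8a or Cd8b1, the chains of the CD8 coreceptor, was seen in 27.6% of control and 5.90% of IR T cells. NK cells, taken as background, had 1.17% and 0.686%. Foxp3, the master regulator of regulatory T cells, was seen in 2.25% [1.78, 2.81] and 4.59% [4.12, 5.10] of T cells, against 0 of 343 and 0.320% of NK cells. Cd4 was seen in 13.9% [12.7, 15.1] and 15.7% [14.9, 16.6] of T cells, against 0 of 343 and 0.595% of NK cells. Cdkn1a was seen in 0.119% of control and 17.5% of IR T cells, against 0 of 343 and 14.7% of NK cells. Without thinning the T cell shares were 39.8% and 10.6% for CD8 genes, 6.26% and 9.53% for Foxp3, 39.8% and 35.9% for Cd4, and 0.409% and 34.1% for Cdkn1a, at median UMI numbers of 5191 and 3070.5 in T cells and 3889 and 2688 in NK cells.

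**Figure D2:**
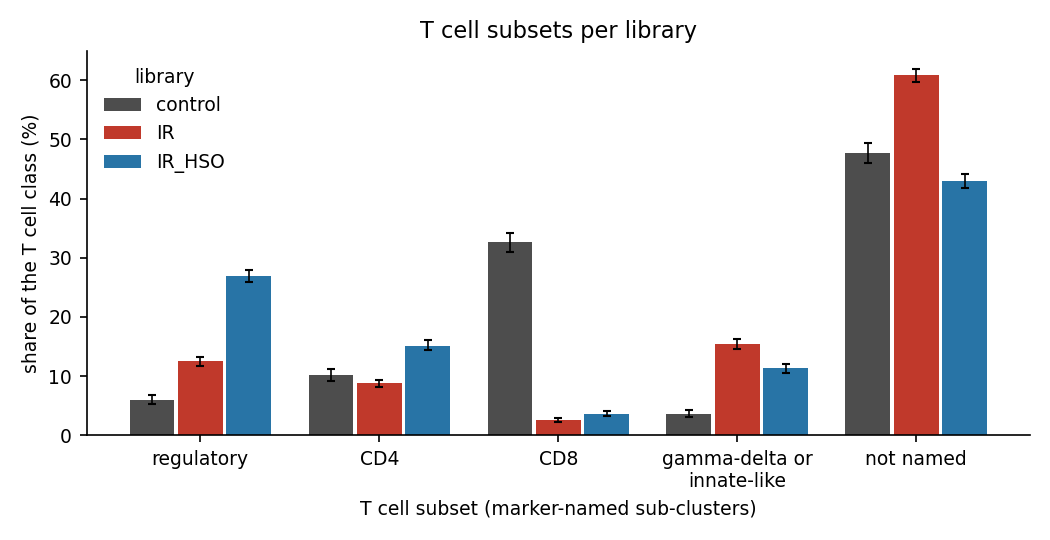
Bars give the share of the T cell class in percent for marker-named subsets in each library, with exact 95% binomial intervals that cover counting error only. CD8 sub-clusters fell by 3.70 on the log2 scale from control to IR, and regulatory sub-clusters were highest in IR_HSO at 26.9%.

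Of the 21 measured p53 targets in T cells, 17 were at least 1.5-fold higher in IR than in control and 4 lay between, with a median log2 ratio of 1.39 [1.27, 1.57] that lay above all 10000 random lists. The median over all genes of the class was 0.15 in this comparison. Cdkn1a (ENSMUSG00000023067) went from 1.14 to 216 CPM, and Phlda3, a brake on Akt signalling, was 55.2-fold higher. Zmat3, an RNA-binding p53 target, was 8.72-fold higher, the stress sensor Sesn2 7.69-fold, and Plk2 5.31-fold. The death effectors Bbc3 and Fas were 4.34-fold [3.94, 4.79] and 2.68-fold higher, Apaf1 2.42-fold and Pmaip1 2.01-fold. Aen, Polk, Ccng1, Tnfrsf10b, Trp53inp1, Rps27l and Mdm2, whose product degrades p53, were between 1.74-fold and 3.75-fold higher. Ddb2, Btg2, Tigar and Sesn1 had ratios of 1.49, 1.24, 0.971 and 0.772. Within subsets the list median was 0.81 in regulatory, 0.89 in CD4, 1.34 in CD8, 1.45 in gamma-delta or innate-like and 1.73 in other T cells. Regulatory cells lay in T cell 00 and 14, which held 95 and 111 cells of control and 843 and 148 of IR, and the median was 0.82 in each of these sub-clusters.

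**Figure D3:**
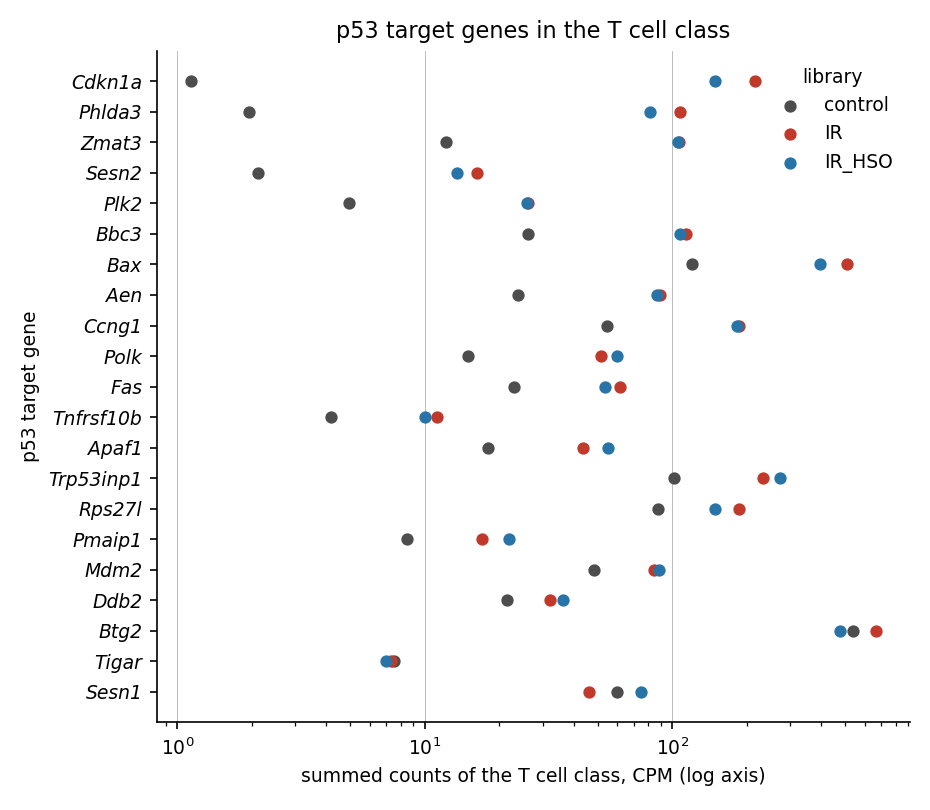
Points give summed counts of the T cell class in CPM on a log axis for the measured p53 targets in control, IR and IR_HSO. Cdkn1a lay at 1.14 CPM in control, 216 in IR and 148 in IR_HSO.

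Part of the genes of cell death and survival were higher in IR T cells. Pro-apoptotic genes had a median of 0.50, with 7 of 15 higher, and anti-apoptotic genes one of 0.49, with 4 of 10 higher. Among the latter, Bcl2, which blocks mitochondrial death, was 5.18-fold [5.02, 5.34] higher and Bcl2l1 3.02-fold. Survival cytokine receptors had a median of 0.54 with 2 of 8 higher, which were Il2rb at 3.44-fold and Bcl2. DNA damage sensing and repair genes had a median of 0.17, where 4 of 23 were higher and 19 lay between. Among the 4, in a class that left out T cell 20, were the checkpoint kinase Chek1 at 4.61-fold, Brca2 at 2.46-fold and Brca1 at 2.32-fold.

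Proliferation genes had a median of 1.02 [0.92, 1.08] in T cells, with 18 of 20 higher in IR and 2 between, in a class that left out the cycling sub-cluster T cell 20 with its 124 cells of control and 5 of IR. With these cells counted as T cells the median was -0.07 [-0.15, -0.01], so the direction rests on the naming of this sub-cluster. Without T cell 20, Stmn1, a microtubule regulator of mitosis, was 3.04-fold higher, Top2a, which untangles replicated DNA, 3.03-fold, Nusap1 3.13-fold and Tyms 2.82-fold. Thinned cells with a UMI of at least 2 proliferation genes were 26.1% [24.6, 27.6] of control and 35.0% [33.9, 36.1] of IR T cells, and 28.0% [26.5, 29.5] and 35.0% with T cell 20 counted. NK cells had 47.8% and 43.5%, and unthinned T cells 86.3% and 72.7%, the other order, so no order of cycling cells is read from this measure. Mki67 or Top2a was seen in 2.07% and 5.52% of thinned T cells, 4.08% [3.44, 4.79] and 5.54% [5.02, 6.09] with T cell 20 counted, and 1.46% and 4.12% of NK cells. B cells with at least 2 proliferation genes were 16.3% and 21.6% [14.0, 30.8], so a difference was not detectable at that depth. Interferon response genes had a median of 0.84 [0.77, 0.94], with 15 of 23 higher, among them the chemokine Cxcl10 at 16.9-fold and the antiviral genes Mx1 at 5.66-fold, Ifit3 at 4.51-fold and Rsad2 at 4.29-fold. NF-kB and inflammatory genes had a median of 0.63, where 8 of 16 were higher and 1 was lower, with Cxcl2 at 5.18-fold and Bcl3 at 2.89-fold.

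Effector and memory genes had a higher median in the IR T cell class, though not within each subset, and naive markers were mixed. Effector and memory genes had a median of 0.68, with 9 of 14 higher and 1 lower, among them the chemokine receptor Ccr2 at 3.77-fold, Il2rb, Id2 at 3.38-fold and Ly6a at 2.57-fold. Their median was 0.03 in regulatory, 0.27 in CD4, 0.19 in CD8, 0.04 in gamma-delta or innate-like and 1.32 in other T cells. Part of these transcripts was also found in IR B cells, where Il2rb stood at 100 CPM against 460 in IR T cells, Id2 at 56.2 against 470, Ccr2 at 12.5 against 63.9 and Ly6a at 622 against 271. Naive and homing genes had a median of -0.28, with 2 higher, 1 lower and 9 between. Dapl1, a marker of naive CD8 cells, was 7.13-fold lower, and Igfbp4 was 3.34-fold higher. T cell receptor signalling genes had a median of 0.23 with 5 of 17 higher, among them the costimulatory receptors Tnfrsf4 at 4.38-fold and Tnfrsf9 at 2.98-fold and the interleukin 2 receptor gene Il2ra at 3.73-fold. Inhibitory receptor genes had a median of 0.72, with 5 of 8 higher, such as Entpd1 at 2.90-fold, Cd160 at 2.30-fold and Ctla4 at 2.11-fold.

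Cytotoxicity genes had a median of 1.27 [1.24, 1.30] in T cells, with 7 of 11 higher and 1 lower in IR, beside the higher NK share. Of sub-clusters with such genes on top, T cell 02, 06 and 23 held 2.22%, 1.32% and 0.439% of control T cells. In IR they held 13.7%, 7.11% and 0.655%, while T cell 17 went from 0.965% to 0.340%. The class median thus also compares different mixes of T cells. Gzmb, a granzyme that starts apoptosis in target cells, was 34.0-fold higher at 140 CPM, Fasl was 5.44-fold and Ifng 3.87-fold higher. Gzma was 10.3-fold higher at 244 CPM, a level also found in IR B cells, which should lack it, at 222 CPM. After thinning, Gzma was seen in 20.2% of IR T cells and 20.6% of IR B cells, and in 79.9% of IR NK cells. Gzmb stood at 21.9 CPM in IR B cells.

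MHC class II and B cell receptor genes had lower medians in T cells of IR, beside the lower B cell share. MHC class II genes, which present antigen on B and dendritic cells, had a median of -1.71 [-1.81, -1.59], with 6 of 10 lower, and a median of -2.12 in NK cells. H2-Aa was 11.5-fold and H2-Ab1 10.1-fold lower in T cells. Without thinning, H2-Aa was seen in 25.4% of control T cells, 24.9% of NK cells and 98.7% of B cells. H2-Ab1 was seen in 25.6%, 24.3% and 98.4%. Shares so alike in T and NK cells are those of free RNA, so the lower levels are not read as a change of T cell expression. B cell receptor genes had a median of -0.77, with 4 of 8 lower, and the B cell marker Cd79a was seen in 2.84% of thinned control T cells and 0.208% of IR T cells. Immunoglobulin heavy constant genes had a median of 1.45, with 4 of 6 higher, and Igkc was seen in 29.7% and 68.6% of T cells and 28.3% and 69.9% of NK cells, alike in both classes.

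Metabolic and stress lists were closer to 0 in this comparison. Fatty acid oxidation genes had a median of 0.35 with 2 of 14 higher, Fabp5 at 1.86-fold and Cpt1a, the gate of mitochondrial fatty acid uptake, at 1.85-fold. Antioxidant genes had a median of 0.26 with 2 of 14 higher, Txn1 at 1.61-fold and Sod2 at 1.55-fold. Oxidative phosphorylation genes had a median of 0.20, fatty acid and sterol synthesis genes 0.07 and MHC class I genes 0.30, with all of their 24, 16 and 13 measured members between. Unfolded protein response genes had a median of 0.23, with 2 of 12 higher, Xbp1 at 1.56-fold and Herpud1 at 1.53-fold, but -0.14 with T cell 20 counted and -0.08 under the stricter cell filter. Immediate-early and stress genes had a median of 0.05, with 3 of 19 higher, among them the phosphatase gene Dusp1 at 3.15-fold, and -0.10 after centring on all genes.

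Digestive enzymes and secreted proteins of the exocrine pancreas made up 5 of the 6 largest ratios in T cells, with Cdkn1a in the fourth place. Ctrb1 was at least 2336-fold higher in IR, Try5 at least 1122-fold, Reg2 at least 762-fold, Reg3b at least 577-fold and Try4 at least 521-fold, each with 0 UMIs in control T cells. Ctrb1 was found in 66.0% of IR T cells, 64.4% of NK cells and 68.0% of B cells without thinning. It stood at 380 CPM in IR T cells, 387 in NK cells, 365 in B cells and 92.5 in plasma cells. Levels so alike in T, NK and B cells are those of free RNA and argue against expression by T cells themselves. These ratios are therefore not read as a response of T cells. An unnamed cluster with acinar cell genes held 0 cells of control and 44 of IR. Over all barcodes of a library, 12 pancreatic genes held 89 UMIs in control and 240957 in IR. Besides H2-Aa, H2-Ab1 and Dapl1, the lowest ratios were those of Cd8b1 at 5.61-fold, Cd8a at 4.02-fold and Mir6236, which lies in ribosomal RNA, at 3.91-fold lower. Try4 and Try5 are close paralogues, so the split between them is uncertain.

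In the B cell class of IR, with 103 cells, transcripts of p53 targets were higher as well. The list median was 1.38 [0.94, 1.67], with 15 of 21 higher, 2 lower and 4 between, above all 10000 random lists. Phlda3 was 253-fold [86.0, 1011] higher, Cdkn1a 41.9-fold [24.7, 70.8], Bbc3 13.7-fold, Bax 3.88-fold [3.25, 4.61], Ccng1 3.82-fold and Trp53inp1 3.18-fold. Plk2 had a ratio of 0.531 [0.213, 1.10]. Cd3 genes, which B cells should lack, stood in IR B cells at 12.7% of their T cell level, and Cdkn1a stood at 43.4%, Phlda3 at 63.9% and Bax at 86.5%. With T cell RNA taken out at the Cd3 level the median was 1.35. Other sources of free RNA were not set apart. Interferon genes had a median of 1.33 [1.03, 1.77], with 18 of 23 higher, such as Ifit3 at 11.0-fold and Ifit2 at 9.45-fold. Immediate-early genes had a median of -0.45, with 1 higher, 8 lower and 10 between, and Klf6, Fos and Fosb had ratios of 0.383, 0.406 and 0.423. Of these cells 39 lay in B cell sub-cluster 09, which held 12 control cells.

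Lists drawn up for T and NK cells had higher medians in the IR B cell class. Not all of this need come from T or NK cells, since Ly6a stood higher in IR B cells than in IR T cells. The median was 3.22 for cytotoxicity with all 9 measured members higher, and all 12 measured effector and memory genes were higher too, Il2rb at 21.1-fold. Medians were 1.53 for T cell receptor signalling and 1.58 for inhibitory receptors. Antigen presentation genes of class II had a median of 0.00 with 12 of 13 between, those of class I 0.43 with 3 of 13 higher, Nlrc5 at 1.89-fold, H2-Q7 at 1.64-fold and H2-K1 at 1.52-fold, and B cell receptor genes -0.11 with 2 higher and 2 lower of 16. Medians were 0.43 [-0.11, 0.70] for proliferation, -0.13 for DNA damage, -0.03 for pro-apoptotic, 0.17 for anti-apoptotic, 0.41 for NF-kB, 0.10 for antioxidant and 0.49 [-0.20, 0.58] for fatty acid oxidation genes. They were -0.00 for fatty acid synthesis, 0.16 for oxidative phosphorylation, -0.52 for naive and homing, 0.48 for immunoglobulin heavy constant, 0.03 for unfolded protein and 0.27 for survival receptor genes.

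Single genes with the largest ratios in B cells were again pancreatic. As in T cells, they are not read as expression by the class. Ctrb1 was at least 1796-fold higher in IR, Try5 at least 844-fold, Reg2 at least 706-fold, Try4 at least 537-fold and Reg3b at least 399-fold, and Prss2, with 1 control UMI, was 1612-fold [271, 65454] higher. Rgs2, a brake on G protein signalling, was 4.18-fold [2.57, 7.32] lower, and Kmo, an enzyme of tryptophan breakdown, 4.26-fold lower. The histone genes H2ac24 and H1f5 were 3.80-fold and 3.07-fold lower, Mir6236 3.36-fold and the copper chaperone Atox1 2.96-fold.

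HSO in irradiated mice went with a larger share of regulatory T cells and lower medians of proliferation and immediate-early genes, while the median of p53 targets in T cells stood near 0. Regulatory sub-clusters held 12.5% of T cells in IR and 26.9% in IR_HSO, a log2 ratio of 1.11 [1.01, 1.21]. Proliferation genes in T cells had a median of -1.02 [-1.11, -0.88] in IR_HSO over IR, immediate-early genes one of -0.59 [-0.64, -0.53], and p53 targets one of -0.04 [-0.09, 0.01]. B cell-like cells were 0.372% [0.260, 0.514] of IR_HSO, or 36 cells, against 0.893% in IR, a log2 ratio of -1.27 [-1.81, -0.72]. This lower share holds for kept cells only, since the filter removed 105 B cells by their own markers in IR_HSO and 8 in IR. Over all barcodes the 10 B cell markers differed less, with 111 CPM in IR_HSO and 177 in IR. T cell-like cells were 72.7% [71.8, 73.6], a log2 ratio of 0.08 [0.05, 0.10] over IR.

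Among the other classes, NK cell-like cells were 2657 in IR and 1858, or 19.2%, in IR_HSO, and plasma cell-like cells 2.45% and 3.43%, or 2.60% and 2.91% under the stricter cell filter. Conventional dendritic cell-like cells were 0.919% and 0.846%, monocytes 1 and 2 cells and plasmacytoid dendritic cells 0 in both. CD8 sub-clusters held 2.52% and 3.61% of T cells, a log2 ratio of 0.52 [0.26, 0.78], CD4 sub-clusters 8.76% and 15.2%, and gamma-delta or innate-like ones 15.4% and 11.3%. T cells of IR_HSO lay most often in sub-clusters T cell 00 with 26.3% and T cell 03 with 17.0%, where IR had 10.6% and 7.46%. T cell 01, the largest in IR, went from 25.3% to 2.61%, and the other regulatory sub-cluster, T cell 14, from 1.86% to 0.653%.

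After thinning, which left out 397 of 7042 IR_HSO T cells, Foxp3 was seen in 4.59% of IR and 10.0% [9.31, 10.8] of IR_HSO T cells, against 0.320% and 0.710% of NK cells. Pdcd1, which encodes the inhibitory receptor PD-1, was seen in 1.25% and 4.26% of T cells and in 0.0915% and 0.237% of NK cells. Cd4 was seen in 15.7% [14.9, 16.6] and 16.9% [16.1, 17.9] of T cells and 0.595% and 1.18% of NK cells, a smaller difference than that of the CD4 sub-clusters. CD8 genes were seen in 5.90% and 6.44% of T cells and 0.686% and 1.01% of NK cells, and Cdkn1a in 17.5% and 12.4% of T cells and 14.7% and 16.6% of NK cells. Unthinned T cell shares in IR_HSO were 19.1% for Foxp3, 10.2% for Pdcd1, 11.6% for CD8 genes and 27.6% for Cdkn1a, at a median of 3121.5 UMIs in T cells and 3466.5 in NK cells. Barcodes with 10% or more mitochondrial UMIs were 4.76% in IR and 16.5% in IR_HSO, and the shares above leave them out.

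**Figure D4:**
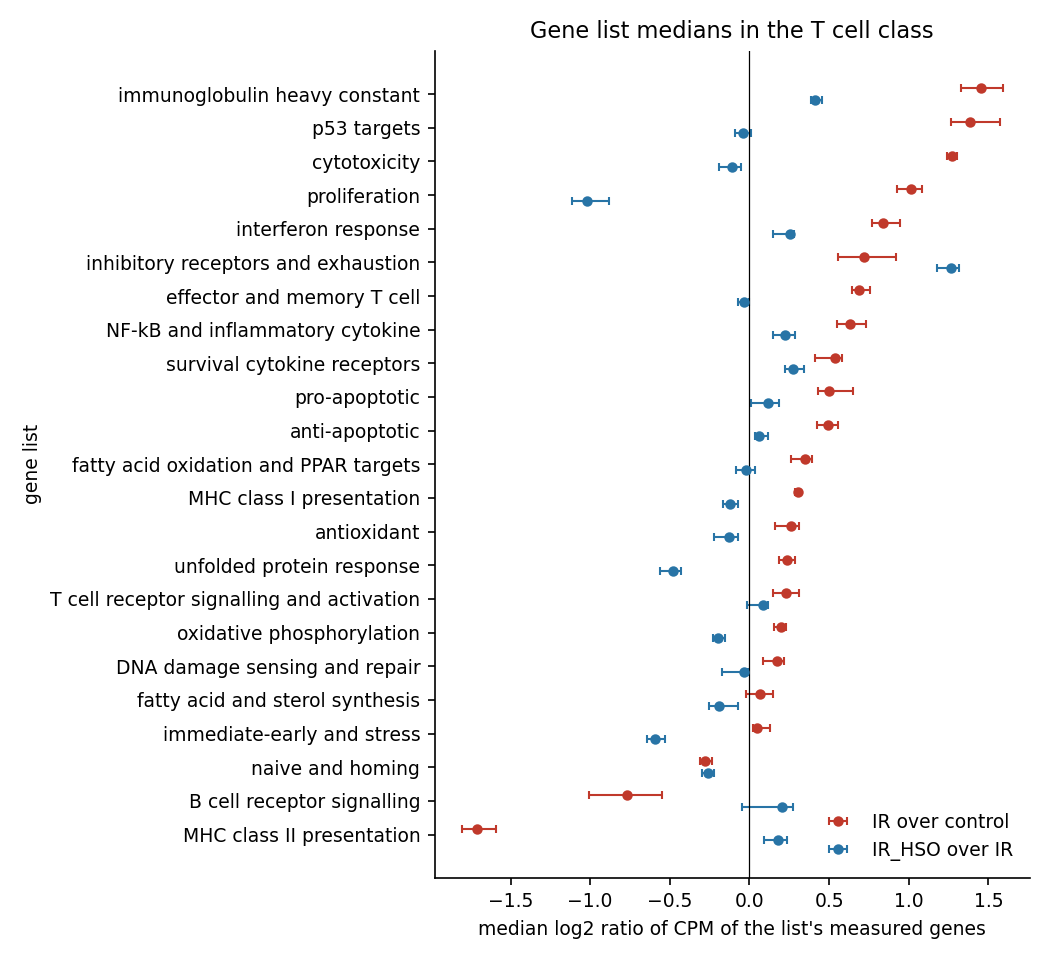
Points give the median log2 ratio of each gene list in the T cell class, for IR over control and IR_HSO over IR, with 95% Poisson resampling intervals. Inhibitory receptors lay at 0.72 and 1.26 in these comparisons and p53 targets at 1.39 and -0.04.

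Of the p53 targets in T cells, 20 of 21 lay between the 1.5-fold bounds in IR_HSO over IR. Sesn1, a stress-induced brake on growth signalling, was 1.62-fold [1.51, 1.75] higher, while Cdkn1a had a ratio of 0.688 [0.660, 0.717], Btg2 0.718, Phlda3 0.755 and Bax 0.775. Pmaip1 had a ratio of 1.29, and Mdm2, Bbc3, Aen, Ccng1, Zmat3 and Plk2 lay between 0.952 and 1.05. The list median was -0.14 in regulatory, 0.01 in CD4, 0.10 in CD8 and 0.03 in gamma-delta or innate-like T cells. DNA damage genes had a median of -0.04, with 4 of 23 lower and 19 between, where Chek1, H2ax and Chek2 had ratios of 0.388, 0.533 and 0.527. Pro-apoptotic genes had a median of 0.12 with 14 of 15 between and Cycs, which encodes cytochrome c, at 0.580. Anti-apoptotic genes had a median of 0.06 with all 10 between, and survival receptors one of 0.27 with all 8 between.

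Cell cycle genes were lower in IR_HSO for 17 of 20 proliferation genes in T cells, and 3 lay between. Ube2c, which drives exit from mitosis, had a ratio of 0.241, Cenpf 0.285, the mitotic kinase Cdk1 0.311 and Top2a 0.359. T cells with a UMI of at least 2 proliferation genes were 35.0% [33.9, 36.1] of thinned cells in IR and 27.5% [26.4, 28.6] in IR_HSO, beside 43.5% and 31.7% of NK cells. Without thinning the T cell shares were 72.7% and 69.9%, in the same order but closer. Mki67 or Top2a was seen in 5.52% and 3.42% of T cells and 4.12% and 1.84% of NK cells. The cycling sub-clusters T cell 15 and 22 held 2.15% and 1.32% of IR T cells and 0.838% and 0.241% of IR_HSO T cells. Within named subsets the list median was -0.09 in regulatory, -0.20 in CD4, -0.55 in CD8 and -0.90 in gamma-delta or innate-like T cells.

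Part of the stress genes were lower in IR_HSO. Of 19 immediate-early and stress genes in T cells, 10 were lower in IR_HSO and 9 lay between. The heat shock genes Hspa1a and Hsp90aa1 had ratios of 0.432 and 0.445, and the growth-signal transcription factors Fos and Jun 0.453 and 0.471. Within subsets the median was -0.49 in regulatory, -0.74 in CD4, -0.61 in CD8 and -0.69 in gamma-delta or innate-like T cells. Unfolded protein response genes had a median of -0.48 [-0.56, -0.43], with 4 of 12 lower and 8 between, among them the chaperones Hsp90b1 at 0.538 and Sdf2l1 at 0.550. These genes moved beside the ribosomal RNA share of the library, which was 1.23% in IR and 4.99% in IR_HSO, and the mitochondrial share of 2.37% and 3.84%.

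Inhibitory receptors had a median of 1.26 [1.18, 1.32] in T cells of IR_HSO over IR, with 6 of 9 higher and 3 between. Tigit was 5.39-fold, Pdcd1 2.89-fold, Lag3 2.80-fold and Ctla4 2.51-fold higher. Their median within subsets was 0.41 in regulatory, 0.72 in CD4, 0.66 in CD8 and 0.98 in gamma-delta or innate-like T cells. T cell receptor signalling genes had a median of 0.09, with 2 of 17 higher, Tnfrsf4 at 1.95-fold and Tnfrsf9 at 1.69-fold, and 2 lower, the early activation marker Cd69 at 0.612 and Nr4a3 at 0.613. Naive and homing genes had a median of -0.26, with 4 of 12 lower, Dapl1 at 0.340, Igfbp4 at 0.602, Klf2 at 0.643 and Lef1 at 0.651. Effector and memory genes had a median of -0.03 with 2 of 14 lower, Lgals1 at 0.561 and Ccr2 at 0.591. Cytotoxicity genes had a median of -0.11, with 2 of 11 higher and 2 lower, where Gzmk was 3.42-fold higher and Ifng had a ratio of 0.566.

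Interferon response genes had a median of 0.25 in T cells of IR_HSO over IR, with 2 of 24 higher, Oas1a at 2.62-fold and Ifit3 at 1.59-fold, and 22 between. Their median was 0.14 in regulatory, -0.06 in CD4, -0.07 in CD8 and -0.05 in gamma-delta or innate-like T cells. Among sub-clusters with interferon genes on top, T cell 09 held 1.85% of IR and 4.49% of IR_HSO T cells, and T cell 16 held 1.61% and 1.18%. NF-kB genes had a median of 0.22, with 2 of 16 higher, Bcl3 at 1.81-fold and Cd83 at 1.70-fold. MHC class I genes had a median of -0.12 with H2-Q4 at 1.73-fold higher, MHC class II genes one of 0.18 with H2-Oa at 1.94-fold higher, and B cell receptor genes one of 0.21 with all 5 measured members between. Immunoglobulin heavy constant genes had a median of 0.41, with 2 of 7 higher.

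Lipid and redox genes, of interest for an oil rich in unsaturated fatty acids, moved little. Fatty acid oxidation genes had a median of -0.02 [-0.09, 0.03] in T cells, with 13 of 14 between and the lipid droplet gene Plin2 at 0.566. Fatty acid and sterol synthesis genes had a median of -0.19, with 13 of 15 between, and Idi1 had a ratio of 0.408. Antioxidant genes had a median of -0.13, with 13 of 14 between and Gpx4, which repairs oxidised lipids, 1.51-fold higher. Oxidative phosphorylation genes had a median of -0.20, with 23 of 24 between and Atp5g1 at 0.609.

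The highest ratios in T cells of IR_HSO over IR were those of Mir6236 at 7.43-fold and Rn18s-rs5 at 4.41-fold, both ribosomal RNA. They were followed by the histone gene H2ac24 at 3.88-fold, the detoxifying enzyme gene Gstp1 at 3.86-fold, Atp5g2 at 3.71-fold and Wdr89 at 3.51-fold. The lowest were Hsph1, a heat shock chaperone, at 3.71-fold lower, the tubulins Tuba1b at 3.40-fold and Tuba1a at 2.69-fold, Rnaset2a at 3.16-fold, Mir703 at 3.13-fold and Top2a at 2.78-fold. Tubulin, histone and Hspa1 genes have near-identical copies, so reads can be shared between copies.

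B cells of IR and IR_HSO were spread differently over sub-clusters, with 39 of 103 and 10 of 36 in B cell 09, 26 and 5 in B cell 00 and 7 and 14 in B cell 06. The 36 B cells of IR_HSO gave p53 targets a median of -0.46 [-0.97, -0.13] against IR, with 4 of 21 higher, 9 lower and 8 between, and -0.35 with the 2 members at 0 UMIs held at their bound. Cdkn1a had a ratio of 0.345 [0.105, 0.899], Bax 0.573 [0.391, 0.822] and Trp53inp1 0.528 [0.271, 0.962]. Immediate-early genes had a median of -0.93 [-1.22, -0.58] with 13 of 20 lower and 1 higher, where Hspa1a had a ratio of 0.109 and Hsp90aa1 0.324. Interferon genes had a median of -0.71 with 13 of 23 lower, Isg15 at 0.207, and unfolded protein genes one of -0.92 with 9 of 12 lower, Calr at 0.446. Survival receptor genes had a median of -0.67 with 7 of 10 lower, Tnfrsf13c, the BAFF receptor that keeps B cells alive, at 0.518. Lists drawn up for T and NK cells had lower medians too, at -1.61 for cytotoxicity, -1.26 for T cell receptor signalling and -0.67 for effector and memory genes.

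Medians of the other lists in B cells were 0.01 for DNA damage, 0.19 for pro-apoptotic, -0.27 for anti-apoptotic, -0.41 for proliferation, -0.41 for NF-kB, 0.05 for antioxidant and 0.05 for fatty acid oxidation genes. They were -0.30 for fatty acid synthesis, 0.10 for oxidative phosphorylation, -0.36 for MHC class II, -0.30 for MHC class I, -0.30 for B cell receptor, -0.28 for inhibitory receptor, -0.18 for naive and homing and 0.98 for immunoglobulin heavy constant genes. The intervals of DNA damage, pro-apoptotic, anti-apoptotic, proliferation, antioxidant, both fatty acid lists, oxidative phosphorylation, inhibitory receptors, naive and homing and immunoglobulin genes include 0, so no difference was detectable at this depth. Thinned B cells with a UMI of at least 2 proliferation genes, some of them widely expressed, were 21.6% [14.0, 30.8] in IR and 17.1% [6.56, 33.6] in IR_HSO, and those with Mki67 or Top2a 2.94% and 2.86%.

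Among single genes in B cells, Mpdu1, used in protein glycosylation, was at least 6.91-fold higher in IR_HSO. Slc7a7, an amino acid transporter, was 18.7-fold [2.58, 818] higher, Dgkq and Rnaseh1 16.6-fold, and Nav2 and Serpina3f 9.33-fold [1.93, 88.7]. UMIs in IR_HSO and IR were 9 and 1 for Slc7a7, 8 and 1 for Dgkq and Rnaseh1, and 9 and 2 for Nav2 and Serpina3f. Slc7a7 was seen in 11.1% of IR_HSO B cells, so some cells held several of its UMIs, which the interval treats as independent. Serpina3f was seen in 33.4% of IR_HSO NK cells and 16.7% of B cells. With all doublets kept, Nav2 had a log2 ratio of -0.31. Rps6ka5 and Ifi208 were at least 3.06-fold lower, Bcl6, which directs germinal centre B cells, and Ormdl1 at least 2.89-fold, and Egr3 at least 2.73-fold, all with 0 UMIs in IR_HSO. Rgs1 was 18.8-fold [3.18, 762] lower.

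Against control, p53 targets and inhibitory receptors were higher in T cells of IR_HSO. The p53 median was 1.57 [1.43, 1.70] with 18 of 21 higher, Cdkn1a at 130-fold and Bax at 3.27-fold. Inhibitory receptors had a median of 1.70 with all 9 measured members higher, such as Tigit at 6.21-fold and Ctla4 at 5.28-fold. Interferon genes had a median of 1.05 with 18 of 24 higher, and proliferation genes, again without T cell 20, one of -0.01 with 3 higher, 1 lower and 16 between. Mki67 or Top2a was seen in 2.07% of control and 3.42% of IR_HSO thinned T cells. With T cell 20 counted these were 4.08% and 3.52%, the other order. Immediate-early genes had a median of -0.62, with 2 higher, 10 lower and 7 between, where Hspa8 and Fosb had ratios of 0.419 and 0.433 and Dusp1 was 3.64-fold higher. All genes of the class had a median of 0.19 here.

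Further lists in T cells of IR_HSO over control followed. Medians were 1.03 for pro-apoptotic, 0.78 for anti-apoptotic, 0.78 for NF-kB, 0.76 for survival receptor, 0.80 for effector and memory, 1.29 for cytotoxicity and 1.40 for immunoglobulin heavy constant genes. They were -1.51 for MHC class II, -0.67 for B cell receptor, -0.45 for naive and homing and -0.32 for unfolded protein genes. Fatty acid oxidation genes had a median of 0.29 with 5 of 14 higher, Cpt1a at 2.04-fold, and fatty acid and sterol synthesis genes one of -0.11, where Scd2, a fatty acid desaturase, was 1.88-fold higher and Idi1 had a ratio of 0.439. Medians were 0.08 for DNA damage, 0.05 for antioxidant, 0.03 for oxidative phosphorylation, 0.16 for MHC class I and 0.36 for T cell receptor signalling genes. In B cells the p53 median was 0.80 [0.27, 1.12] and the immediate-early median -1.36.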

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

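The tests of T cell subsets, of single sub-clusters and of scaling for p53 targets, and that of depth for regulatory T cells, were given their final form after results had been seen; those of the cell filter, of naming and of the mitochondrial filter were set before. For p53 targets the bound was moved from a median above 0.7 to an interval above 0.3 once subset medians were known, and the interval of the regulatory subset reaches below 0.7.

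B cells were nearly absent from both irradiated libraries. Loss at the cell filter is argued against, since over all deposited barcodes the summed CPM of the 10 B cell markers had a log2 ratio of -4.58 [-4.61, -4.55] for IR over control. Removed barcodes, which weigh little in such a sum, held 8 B cells by their own markers in IR. Naming of clusters is argued against too, since shares without clusters gave -5.67 [-5.94, -5.39]. Death of irradiated B cells may be behind the difference, as a hypothesis for which no test was set. Loss before the library was made stays open, as does a difference between single mice.

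T cells of IR carried more p53 targets than those of control. A change in the mix of subsets would leave no difference within them, yet the lowest subset median, in regulatory cells, was 0.81 [0.58, 1.22]. Control and IR cells of a subset were spread differently over its sub-clusters, so the mix within a subset differed too. In single sub-clusters with at least 20 cells in both libraries the median lay between 0.82 and 2.08, with intervals that reached down to 0.00 in T cell 21 and 0.15 in T cell 17. Scaling would vanish with centring on all genes, yet the median was then 1.23 [1.12, 1.42]. A DNA damage response in surviving T cells may be behind it, as a hypothesis for which no test was set, and DNA damage sensing and repair genes had a median of 0.17 with 19 of 23 between. With 1 library per group a difference between mice or preparations stays open.

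Regulatory T cells took a larger share in IR_HSO than in IR. Loss of other T cells at the mitochondrial filter is argued against by Foxp3 UMIs per Cd3 UMI over all deposited barcodes, whose log2 ratio was 1.52 [1.44, 1.60] for IR_HSO over IR. Depth per cell is argued against by near-equal median UMI numbers of T cells, 3070.5 in IR and 3121.5 in IR_HSO. Thinned shares of Foxp3 cells gave 1.13 [0.94, 1.31], which adds little, since thinning could hardly change the ratio at such depths. Selective survival of regulatory cells or HSO itself may be behind it, and neither was tested. Library preparation, with 16.5% of barcodes at 10% or more mitochondrial UMIs in IR_HSO, stays open.

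Cytotoxicity genes differed between 2 classes, since the median of IR over control was 1.27 in T cells and -0.12, within 1.5-fold, in NK cells, a difference that was not tested. For IR_HSO over control the median was 1.29 in T cells and -0.52 in NK cells, which was not tested either. Gzma stood at 244 CPM in IR T cells and 222 CPM in IR B cells, which should lack it. Effector and memory genes in IR_HSO over control had medians of 0.80 in T cells and -0.20 in NK cells, again untested. Genes of the exocrine pancreas, outside the comparisons, took 0.474% of all UMIs in IR and 0.833% in IR_HSO against 0.000188% in control. These totals cover all barcodes, also those of the unnamed cluster with acinar cell genes. Within the T cell class the order was the other one, with Ctrb1 at 380 CPM in IR and 220 in IR_HSO, and Try5 at 182 and 76.7.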

How the results depend on the processing

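Alternatives for single genes, T cell lists other than p53 targets, and subset, NK and plasma cell shares were chosen after results were seen, as were those on T cell 20, T cell RNA in B cells, Rn18s-rs5, low-UMI sub-clusters, B cell sub-cluster 09 and regulatory or other sub-clusters alone. Over 12 shares, all 92 alternative values kept their direction, and 16 moved beyond counting error. B cell shares ran from -5.88 to -5.44 for IR over control and from -1.28 to -1.03 for IR_HSO over IR. No setting kept all barcodes, and the removed ones held 8 B cells by their own markers in IR and 105 in IR_HSO. The range for IR_HSO over IR therefore does not show how far that share depends on the filter. CD8 shares ran from -3.83 to -3.55 and from 0.35 to 0.53, and regulatory shares for IR_HSO over IR from 1.01 to 1.11. B cell p53 medians ran from 1.30 to 1.61 and from -0.63 to -0.24. Of 258 values of 22 list medians 194 stayed within counting error, 57 moved beyond it and 7 were reversed, and the p53 median of T cells for IR_HSO over IR, near 0, was of the other sign in 1 moved value. Of 456 values of 48 named genes 287 stayed within counting error, 168 moved beyond it and 1 changed sign, and all 16 values of list counts stayed within 1.5 times the first count.

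The T cell share of IR over control was 0.70 with lymphocytes alone as denominator, 0.65 without low-UMI sub-clusters, 0.66 with the looser filter and 0.71 with T cell 20 counted, against 0.76. For IR_HSO over IR it was 0.13 without low-UMI sub-clusters, 0.04 with both the stricter (0.0366) and the looser (0.0437) filter, 0.11 with doublets kept and 0.12 with each library clustered alone, against 0.08. The regulatory share of IR over control was 1.31 with the looser filter and 1.28 at resolution 2, against 1.05. The plasma cell share of IR over control was 0.51 with each library clustered alone, against 2.20, and that of IR_HSO over IR 0.16 with the stricter filter, against 0.48. The NK cell share was 2.16 without low-UMI sub-clusters, against 2.40, and for IR_HSO over IR -0.11 without them and with the stricter filter, against -0.26. The p53 median of T cells for IR over control was 1.23 after centring and 1.23 without a low-count filter, 1.73 at 20 CPM and 0.81 in regulatory cells alone. For IR_HSO over IR it was 0.02 (0.0179) without Rn18s-rs5 and -0.14 in regulatory cells alone, against -0.04. Immediate-early genes of T cells, IR over control, had -0.10 after centring and -0.03 (-0.0317) without immunoglobulin, haemoglobin, mitochondrial and ribosomal protein genes, against 0.05, since both shift all genes alike. Proliferation genes there had -0.07 (-0.0738) with T cell 20 counted, since 124 cells of control with cycling genes on top then enter the class, 0.20 with the stricter and 0.08 with the looser filter, and 2.68 with each library clustered alone, against 1.02. Unfolded protein genes there had -0.14 with T cell 20 counted, -0.08 (-0.0800) with the stricter and -0.01 (-0.00631) with the looser filter, against 0.23. Effector and memory genes of T cells, IR_HSO over IR, had 0.000434 with the looser filter, against -0.03. Nav2 in B cells, IR_HSO over IR, had -0.31 with doublets kept, against 3.03. Where no reason is given, the cause was not tested.

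With T cell 20 counted, thinned cells with at least 2 proliferation genes were 28.0% of control T cells. Without thinning, cells with at least 2 proliferation genes were 68.5%, 67.0% and 75.0% of B cells and 86.3%, 72.7% and 69.9% of T cells in control, IR and IR_HSO, since more UMIs per cell show more genes. Depth limits B cells most, with 103 cells in IR and 36 in IR_HSO. No paired analysis was possible because each group has 1 library and no result comes from a test.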

Other observations

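No tests beyond those given with the 3 patterns above were run here, and the values that follow were chosen after results were seen. NK cells of the libraries lay in different sub-clusters, those of control mostly in NK cell 07 (197 of 366), those of IR most often in NK cell 00 and 02 (605 and 543 of 2657) and those of IR_HSO in NK cell 01 and 06 (421 and 326 of 1858). NK cells of IR carried p53 targets with a median of 0.79 [0.67, 1.15] over control, where 14 of 21 were higher and 7 lay between. Cdkn1a was 54.3-fold [23.2, 167] higher in them, Bax 3.70-fold, and Phlda3 at least 48.5-fold, with 0 UMIs in control. Gzmb was 3.86-fold higher while the maturation marker Klrg1 had a ratio of 0.444. In IR_HSO over IR the p53 median of NK cells was 0.06, that of interferon genes 0.33 with 9 of 24 higher, such as Rsad2 at 3.11-fold and Ifit3 at 2.84-fold, and that of cytotoxicity genes -0.46, with Ifng at 0.619 and Nkg7 at 0.638. Immediate-early genes were lower in IR_HSO than in IR in all 4 classes examined, with medians of -0.59 in T cells, -0.59 in NK cells, -0.93 in B cells and -0.51 in plasma cells.

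Plasma cells of IR and control, 283 and 45 cells, differed in IgG genes, while Ighm took 8.37% and 7.40% of their UMIs. Ighg3 was 118-fold [89.1, 161] and Ighg1 52.8-fold [27.8, 116] higher, and Ighg2c had a ratio of 0.165. These intervals treat UMIs as independent, though a single plasma cell can hold many UMIs of such a gene. A few cells could therefore set these ratios, and the intervals are too narrow for a difference between cells. Their unfolded protein genes had a median of -0.76 and their p53 targets one of 0.17 in IR over control, where all genes had -0.47. Median UMI numbers of plasma cells were 20114, 12933 and 5359 in control, IR and IR_HSO. The class joins 2 clusters with medians of 16629.5 and 2770 UMIs, and the second held 4 of 45, 76 of 283 and 162 of 332 cells, so these values also compare different mixes. A sub-cluster of CD4 T cells with Il21, Pdcd1 and Lag3 among its top genes, T cell 12, held 0.497% of control, 0.718% of IR and 4.15% of IR_HSO T cells.

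Stromal cells were 30, 180 and 59 in control, IR and IR_HSO, and an unnamed cluster with acinar cell genes held 0, 44 and 41 cells. Thinned NK cells with at least 2 proliferation genes were 47.8%, 43.5% and 31.7%, an order that goes against their CPM between control and IR, so none is read from it. Removed barcodes held 961 T cells by their own markers in IR_HSO, against 364 in IR and 158 in control. They held 105, 8 and 95 B cells, 393, 184 and 20 NK cells, and 396, 57 and 15 plasma cells in IR_HSO, IR and control.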
